A study of Homo sapiens with 20 samples.

How the data were processed

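RNA was compared on 20 Affymetrix oligonucleotide arrays of 12626 probe sets, 1 array per sample, from 2 lines of U2-OS osteosarcoma cells. The first line carried ERα and the other ERβ in the form named 1-530, each at low levels per the labels. Each line had 5 groups of 2 arrays: vehicle (EtOH), and E2 at 10 nM for 4, 8, 24 and 48 h. The titles of 4 E2 arrays of the ERβ line carry no replicate number, and these are called replicate 1. The labels give no time for the vehicle, so changes at 24 and 48 h may include effects of time in culture. The labels also do not say whether replicates were separate cultures, so p-values measure the spread between these arrays. Each receptor is in 1 line, so receptor and clone run together, and hybridisation dates are not given in the sources used here. A difference between the lines therefore cannot be told apart from a difference between clones, or between batches that follow the lines.

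The values deposited by the authors are linear signal intensity per probe set. The software and the background method are not given in the sources used here. Negative numbers made up part of the values (17.8% at or below 0), as an average of perfect match minus mismatch would give. The authors had scaled the arrays, since the 2% trimmed mean of each array lay between 1501.09 and 1501.25. No further normalization was applied for the main results. Detection calls were not given in the files.

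Values below 0 were set to 0, an offset of 156.5 (the 20th percentile of the positive values) was added, and log2 was taken. Log2 changes are therefore compressed for genes near or below the offset, and understate the change in intensity there. The 67 control probe sets and the 40% of the others with the lowest mean (under 247.8) were left out. Of 12626 probe sets, 7535 were tested. Of these, 6682 carried 1 gene symbol (5482 genes), 355 carried several and 498 carried none. Symbols were looked up by Entrez ID in the RefSeq table of GRCh38.p14, where 6681 of the 6682 IDs were found and 0 symbols differed. Probe sets with several symbols are counted but not named by gene, apart from a KLRC probe set.

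A linear model with 10 group means was fitted in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a mean-variance trend (residual df 10, prior df 3.79). The comparisons were E2 against vehicle at each time in each line, an F test over the 4 times in each line, and the late mean (24 and 48 h) against the early mean (4 and 8 h). The difference in E2 effect between lines was tested at each time and with an F test, and the vehicle arrays of the lines were compared. P-values were adjusted by Benjamini-Hochberg within each comparison, and adjusted p under 0.05 counts as changed. Values are means of 2 arrays, ± is the SD over the 2 arrays for intensities, and SE is the moderated standard error of a log2 change. The number of arrays, 2 per group, limits the precision.

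Named genes followed a rule: per line and direction, the 12 genes with 1 symbol and the largest log2 change at any time where they passed. At that time both E2 arrays also had to lie on the same side of both vehicle arrays. Each gene so named had its largest passing change at 24 or 48 h. Genes named for their calls at 4 or 8 h were chosen after their values were seen. Gene lists (24 of them) written from general knowledge were tested with camera at a preset inter-gene correlation of 0.01, on the probe set with the highest mean per gene. Adjusted p was taken over all 144 tests, and a second adjusted p with the correlation estimated per list is given beside it. Camera ranks a list against the other genes, so its direction can differ from the sign of the median or mean.

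The grouping, comparisons, rule for changed genes and most alternatives were written before the data were examined. The alternatives were a smaller offset (31.8, the 5th percentile), a floor in place of the offset, quantile normalization, median centring, no filter (12559 probe sets), a stricter filter (60%, leaving 5024), each line fitted alone, no trend, a replicate block, a 2-fold minimum, estimated list correlation, the mean of probe sets per gene, and leaving out each array in turn. Another 2, a crossed replicate pairing in the ERα line and a spike-in covariate, were chosen after seeing the data. The pipeline was tested on simulated data with 50 planted changes at each of 4 fold sizes among 7535 probe sets. In the ERα line at 24 h it recovered 36% of the planted 1.5-fold changes, 76% of the 2-fold changes and 96% of the 3-fold changes, and in the ERβ line 52%, 82% and 90%. A planted 2-fold difference between the lines was recovered by the F test in 46% of cases when planted in the ERα line and 58% in the ERβ line. False calls were 9 of 161 and 14 of 175 at 24 h in the ERα and ERβ line. The simulated noise was independent between probe sets, while 21.8% of the residual variance of these arrays lay along 1 shared axis. Recovery in the data may therefore differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates were not used, since the files name no build.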

Results

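The comparisons address which genes E2 moves in U2-OS cells that carry ERα or ERβ, how early they move, and whether the receptors move the same genes. The receptor probe sets given by line here separated the lines. The brightest ESR1 probe set read 26067 ± 915 in vehicle-treated ERα cells and 525 ± 36 in ERβ cells, a log2 difference (ERβ minus ERα) of -5.27 (SE 0.55, adjusted p 4.8e-06 in limma). Of the ESR2 probe sets, 1 read 3816 ± 177 in ERβ cells and 853 ± 129 in ERα cells, a log2 difference of 1.98 (SE 0.20, adjusted p 4.4e-06), and 1 read 4085 ± 467 and 33.6 ± 309, a log2 difference of 4.06 (SE 0.39, adjusted p 2.5e-06). Whether these probe sets measure the transfected forms is not given in the sources used here. Signals of different probe sets cannot be compared, so these values do not say which receptor was more abundant.

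In ERα cells, KRT19, a keratin of simple epithelia, rose with E2 from 489 ± 154 in vehicle to 8722 ± 2075 at 24 h, a log2 change of 3.78 (SE 0.21, adjusted p 2.3e-07). CCN5, a secreted matricellular protein, rose from 83 ± 161 to 2713 ± 212 at 48 h (log2 change 3.61, SE 0.27, adjusted p 4.2e-06). MSMB, a protein secreted by the prostate, rose from 107 ± 52 to 2811 ± 63.2 at 48 h (log2 change 3.51, SE 0.24). TFF1, a trefoil peptide of mucus and a classical estrogen target, rose by 2.88 at 48 h. SERPINA6, the corticosteroid carrier of plasma, rose by 2.76, and PTGS2, which makes prostaglandins, by 2.45. TCN1, a cobalamin carrier, rose by 2.24, and IL24, a cytokine, by 2.22 at 24 h, on a probe set whose suffix marks possible matches to related transcripts. ITGA6, a laminin receptor subunit, rose by 1.65. These 9 genes stayed past the threshold in every alternative run, leaving out single arrays included. The remaining 3 genes named by the rule were less firm: S100A4, a calcium-binding protein, rose by 2.13 (SE 0.61), SYT5, a synaptotagmin, by 1.72, and NCAM1, an adhesion molecule, by 1.71. The S100A4 probe set also carries a cautionary suffix, though a different one (r, against f for IL24). Another S100A4 probe set changed by 0.01, and 1 of 3 other NCAM1 probe sets changed by -0.17.

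**Figure D1:**
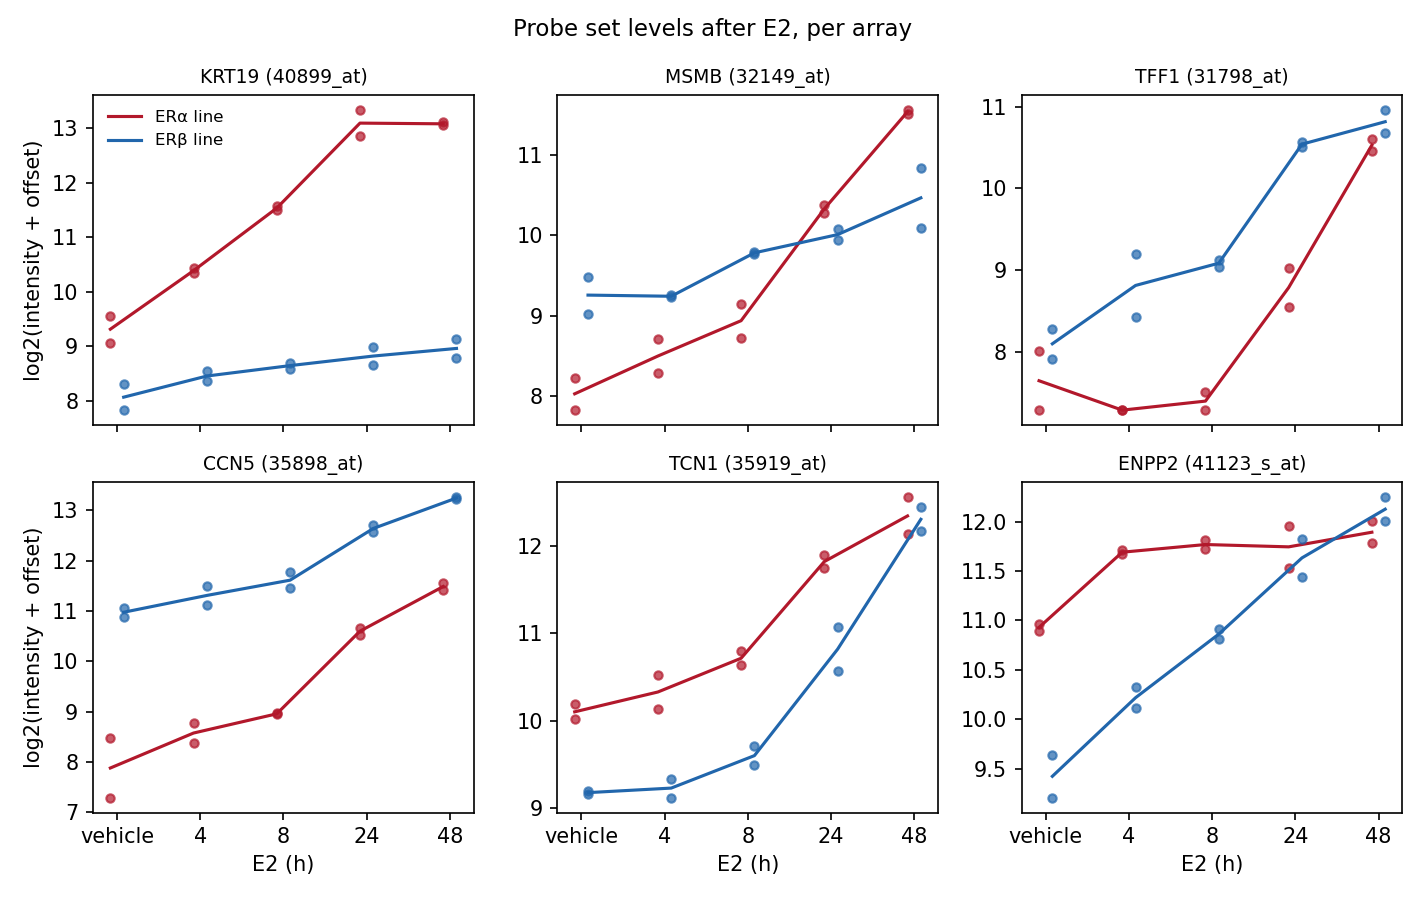
Log2 signal intensity (vertical axis, with offset) of KRT19, MSMB, TFF1, CCN5, TCN1 and ENPP2 against group (vehicle and E2 for 4, 8, 24 and 48 h, evenly spaced). Points are arrays and lines join the means of 2 arrays in each line of cells; KRT19 and MSMB climbed higher in the ERα line, ENPP2 rose more in the ERβ line, and TFF1 ended near the same level in both.

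The falls in ERα cells were smaller and often sat at the bottom of the range. MMP24, a membrane-bound metalloproteinase, fell from 1997 ± 184 in vehicle to 584 ± 75.4 at 48 h, a log2 change of -1.54 (SE 0.23, adjusted p 0.0018). PMPCA, a subunit of the mitochondrial processing peptidase, fell from 1174 ± 166 to 419 ± 111 at 24 h, a log2 change of -1.22 (SE 0.17, adjusted p 0.0015). MMP24 and PMPCA passed in every alternative run; the other 10 named genes lost their call in at least 1 alternative. ETFB, a carrier of electrons from fatty acid oxidation, fell by 2.38, GALK1, the galactose kinase, by 1.97, and CYP11B1, an enzyme of cortisol synthesis, by 1.71. FBP1, an enzyme of gluconeogenesis, fell by 1.35, and ACSM2A, a mitochondrial acyl-CoA ligase, by 1.16. At these times both E2 arrays of ETFB, GALK1, CYP11B1, FBP1 and ACSM2A read below the offset, so the sizes of these 5 changes are uncertain. MARCO, a scavenger receptor, fell by 1.54, CCS, a copper chaperone, by 1.45, and BIK, a pro-apoptotic protein, by 1.13. POLD1, the catalytic subunit of DNA polymerase delta, fell by 1.12, and DHRS3, which reduces retinal, by 1.02.

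Across the array, ERα cells changed little at 4 and 8 h and broadly at 24 and 48 h. Past the threshold were 8 probe sets at 4 h (all rose), 29 at 8 h (27 rose), 794 at 24 h (586 rose) and 685 at 48 h (527 rose). Most late changes were small: 49 at 24 h and 52 at 48 h reached 2-fold. The F test over the 4 times called 323 probe sets. The late counts were lower whichever array was left out. Such a fit also has less power, so a drop need not come from the array itself. The fits without vehicle replicate 1 and without vehicle replicate 2 have the same number of arrays, however. Fewer arrays alone therefore cannot explain the gap between those fits, and the late counts leaned on vehicle replicate 1. Its median intensity, 387.6, was the lowest of all arrays, which ran up to 493.7, and vehicle replicate 2 had 424.2. Whether this low median underlies the gap was not tested. The count at 24 h was 119 without vehicle replicate 1, 202 without 24 h replicate 1 and 209 without 24 h replicate 2, and 733 without vehicle replicate 2. The count at 48 h was 120, 160 and 211 without vehicle replicate 1, 48 h replicate 1 and 48 h replicate 2. The F test called 90 without vehicle replicate 1, 207 without 8 h replicate 2, 153 and 157 without 24 h replicate 1 and 2, and 144 and 162 without 48 h replicate 1 and 2. At 8 h the count was 18 without vehicle replicate 1, 11 without 8 h replicate 1 and 16 without 8 h replicate 2, and at 4 h it was 4 without vehicle replicate 1 and 14 without vehicle replicate 2. The share that rose at 24 h also moved with scaling: with median centring 373 rose and 384 fell, against 586 and 208 on the authors' scale. At 48 h median centring gave 362 and 306, against 527 and 158. Dim probe sets drifted up and bright ones down in ERα cells at each time, always against the same vehicle arrays. The median change was 0.06 in the dimmest 10% and -0.06 in the brightest 10% at 4 h, and 0.12 and -0.09 at 24 h. Quantile normalization left 0.02 and -0.01 at 24 h. In ERβ cells the drift at 24 h went the other way, with -0.04 in the dimmest 10% and 0.07 in the brightest 10%.

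**Figure D2:**
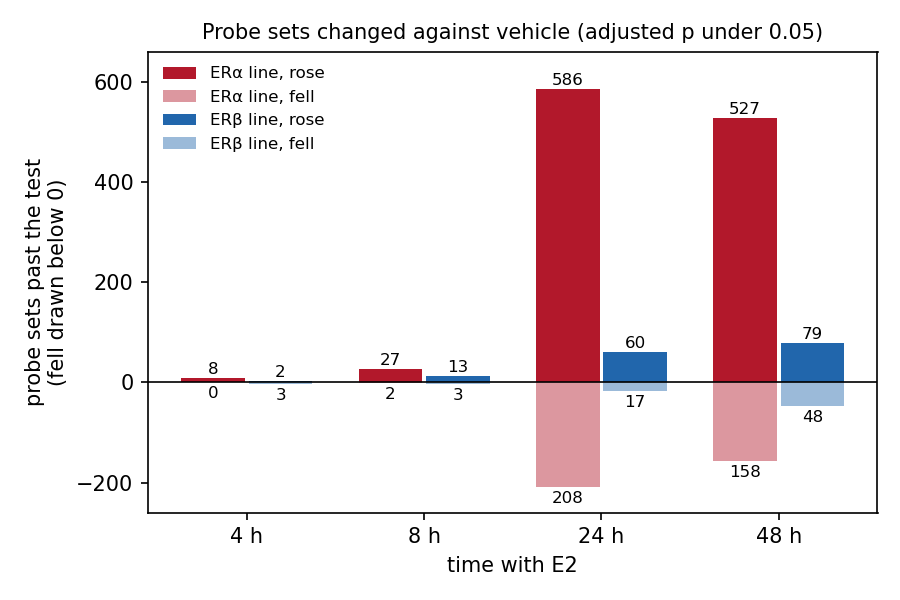
Number of probe sets past adjusted p 0.05 (vertical axis) at 4, 8, 24 and 48 h of E2 in the ERα and ERβ lines, with those that rose drawn above 0 and those that fell below. The ERα line reached 794 at 24 h and the ERβ line 127 at 48 h.

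In ERβ cells, TCN1, the cobalamin carrier, rose with E2 from 422 ± 12.1 in vehicle to 4930 ± 694 at 48 h, a log2 change of 3.13 (SE 0.19, adjusted p 5.8e-07). ENPP2, the enzyme that makes lysophosphatidic acid, rose from 538 ± 145 to 4325 ± 521 (log2 change 2.70, SE 0.17, adjusted p 5.8e-07). TFF1 rose by 2.71, CST5, an inhibitor of cysteine proteases, by 2.31, and CCN5 by 2.27. F13A1, a subunit of the factor that crosslinks fibrin, rose by 2.16. KLRC3, a receptor of natural killer cells, rose by 1.97, on a probe set with the same suffix as that of S100A4. PPP1R12B, a targeting subunit of myosin phosphatase, rose by 1.77, CD34, a surface sialomucin, by 1.54, and BMP6, a bone morphogenetic protein, by 1.44 at 24 h. Of these 10 genes, all but CCN5 passed in every alternative run, and CCN5 lost its call with the smaller offset (adjusted p 0.061). The ENPP2 probe set with the lowest signal had 0.15 and another BMP6 probe set 0.65, neither past the threshold. A probe set of several KLRC genes rose at 48 h in both lines, by 2.72 in ERβ cells and 3.21 in ERα cells. RAD9A, a checkpoint clamp subunit, rose by 1.5 and SGK1, a kinase that controls ion transport, by 1.44, both at 24 h, while another RAD9A probe set changed by -0.22. RAD9A lost its call with the line fitted alone and without vehicle replicate 1, 24 h replicate 1 or 24 h replicate 2 (adjusted p up to 0.14), and SGK1 without vehicle replicate 2 or 24 h replicate 2 (adjusted p up to 0.088).

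Among the falls in ERβ cells, PLIN2, the coat protein of lipid droplets, was the firmest. It went from 8389 ± 264 in vehicle to 4346 ± 326 at 48 h, a log2 change of -0.93 (SE 0.10, adjusted p 0.0002), and was the 1 of 12 named falls that passed in every alternative run. SMAD3, a transducer of TGF-beta signals, fell by 2.44 at 24 h to an intensity below the offset, and its other probe sets read -0.52, -0.07 and -0.65. STX1A, a protein of vesicle fusion, fell by 2.04 at 24 h to a mean of 85.8, below the offset, with 1 E2 array under it. KIF22, a mitotic kinesin, fell by 1.71 at 48 h, with both E2 arrays below the offset. GAS1, a surface protein of growth arrest, fell by 1.17 (adjusted p 0.0034), while another GAS1 probe set had -0.44, not past the threshold. CNN1, a smooth muscle actin binder, fell by 1.22. FBN1, a microfibril protein, fell by 0.90, RHOB, a small GTPase, by 0.89, and SMAD6, an inhibitor of BMP signals, by 0.91, with -0.19 on another SMAD6 probe set, not past the threshold. LIMCH1, an activator of myosin, fell by 1.09, SAMD4A, a translational repressor, by 1.02 and PIAS3, an inhibitor of STAT signals, by 0.94.

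ERβ cells had 5 probe sets past the threshold at 4 h (2 rose), 16 at 8 h (13 rose), 77 at 24 h (60 rose) and 127 at 48 h (79 rose), of which 27 and 40 reached 2-fold at 24 and 48 h. The F test called 102. The count at 4 h was 0 without vehicle replicate 1, where limma with all arrays gave 714 at unadjusted p under 0.05, and 91 without 4 h replicate 1. At 8 h it was 4 without vehicle replicate 1 and 7 without 8 h replicate 2. At 24 h it was 32 and 42 without vehicle replicate 1 and 2, and 39 and 42 without 24 h replicate 1 and 2. At 48 h it was 47 without vehicle replicate 1, 75 without vehicle replicate 2, 55 without 48 h replicate 1 and 205 without 48 h replicate 2. The F test called 64 and 65 without vehicle replicate 1 and 2, and 181 without 4 h replicate 1.

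The earliest genes, named after their values were seen, were few. At 4 h in ERα cells, GRK5, a kinase of G-protein-coupled receptors, rose by 1.23 and 1.14 on its probe sets, PRKX, a cyclic AMP-dependent kinase, by 1.19, and CA12, a carbonic anhydrase, by 1.14 and 1.06. LRIG1, an inhibitor of growth factor receptors, rose by 1.11 and MAF, a transcription factor, by 0.54. GRK5, PRKX, LRIG1, CA12 and MAF passed at all 4 times in ERα cells, with 6 probe sets. At 4 h 1 GRK5 probe set passed in every alternative run, while PRKX, LRIG1 and MAF passed in 4, 5 and 5 of 14 and lost their call with quantile normalization and median centring. The other GRK5 probe set lost its call with the line fitted alone and without ERα vehicle replicate 1, 4 h replicate 1 or 4 h replicate 2 (adjusted p up to 0.10). So did 1 CA12 probe set, and also without the filter (adjusted p up to 0.20), while the other CA12 probe set lost it with the line fitted alone (adjusted p 0.098). At 8 h KRT19 had risen by 2.22, IL24 by 1.87, PTGS2 by 1.49 and RET, a receptor tyrosine kinase, by 0.89, while SLC2A3, a glucose transporter, fell by 0.64 and TGIF1, a repressor of TGF-beta signals, by 0.48. KRT19 and IL24 passed at 8 h in every alternative run. RET passed in 3 of 13 alternatives, and lost its call with either change of offset, with quantile normalization, median centring or the replicate factor, and without any 1 of the vehicle or 8 h arrays (adjusted p up to 0.25). PTGS2 lost its call with the smaller offset and without vehicle replicate 1, 8 h replicate 1 or 8 h replicate 2 (adjusted p up to 0.13). TGIF1 lost its call with the line fitted alone and without any 1 of those 4 arrays (adjusted p up to 0.23), and SLC2A3 without 8 h replicate 2 (adjusted p 0.068). In ERβ cells at 4 h GRK5 rose by 1.03 on 1 probe set (adjusted p 0.050), which passed in 6 of 14 alternatives, and had 0.11 on the other (adjusted p 0.83). SLC7A5, a transporter of large amino acids, rose by 0.42 and passed in 4 of 14 alternatives, while CKB, a creatine kinase, fell by 0.56 and SETDB1, a histone methyltransferase, by 0.83. Without vehicle replicate 1 or 4 h replicate 2, or with the line fitted alone, GRK5, SLC7A5, CKB and SETDB1 all lost their calls. The remaining call there was a probe set without a symbol. At 8 h ENPP2 rose by 1.44, PPP1R12B by 1.29, CA12 by 1.16 and CEBPD, a transcription factor, by 0.81, and SLC2A3 fell by 0.56. The brightest ENPP2 probe set passed at 8 h in every alternative run. Without ERβ 8 h replicate 2 PPP1R12B, CA12, CEBPD and SLC2A3 lost their calls, and without ERβ vehicle replicate 1 CA12, CEBPD and SLC2A3 did. SLC2A3 also lost its call without ERβ 8 h replicate 1, and CEBPD and SLC2A3 with the line fitted alone. The adjusted p then reached 0.059 for PPP1R12B, 0.060 for CA12, 0.27 for CEBPD and 0.21 for SLC2A3. At 8 h 5 probe sets rose and 1 fell in both lines.

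KRT19 rose more in ERα cells: the ERβ effect minus the ERα effect at 24 h was -3.03 (SE 0.30, adjusted p 0.0015 for the F test over 4 times). MSMB gave -2.30 at 48 h and PODXL, a surface sialomucin, -0.85 at 24 h, where it rose by 0.89 in ERα cells and read 0.04 in ERβ cells. ENPP2 went the other way, with 1.74 at 48 h. At single times the difference also passed for PTGS2 (-2.10 at 24 h, adjusted p 0.018), NRIP1, a corepressor of estrogen receptors (-1.01 at 24 h, adjusted p 0.035), RAD9A (1.94, adjusted p 0.029) and ETFB (2.48, adjusted p 0.037). It did not pass for TFF1 (-0.17 at 48 h, adjusted p 0.90), CCN5 (-1.34, adjusted p 0.097) or TCN1 (0.89, adjusted p 0.11). Genes with a call in 1 line did not always differ by this test: CST5 had 1.63 (adjusted p 0.052) and MMP24 1.39 (adjusted p 0.055). MMP24 read -103 ± 214 in vehicle-treated ERβ cells, so it had no room to fall there, and its difference cannot compare the lines. At the single times given, the differences for KRT19 and PODXL passed in every alternative run, while those for MSMB, ENPP2, BMP5, PTGS2, NRIP1, RAD9A and ETFB lost their call in some. The F test was not followed gene by gene in the alternatives. At single times limma called 229 probe sets at 24 h (36 with the higher effect in ERβ cells, 193 with the lower) and 84 at 48 h (13 and 71). With quantile normalization these were 12 and 32 at 24 h and 9 and 24 at 48 h, and with median centring 31 and 45, and 11 and 21. These counts moved widely when 1 array was left out, which also lowers power. Leaving out either ERα vehicle array leaves the same number of arrays, so fewer arrays alone cannot explain the gap between those fits. At 24 h the count was 4, 9 and 4 without ERα vehicle replicate 1, 24 h replicate 1 and 24 h replicate 2, and 389 without ERα vehicle replicate 2. It was 9, 26, 83 and 3 without ERβ vehicle replicate 1 and 2 and ERβ 24 h replicate 1 and 2. At 48 h the count was 6, 3 and 3 without ERα vehicle replicate 1, 48 h replicate 1 and 48 h replicate 2, and 221 without ERα vehicle replicate 2. It was 1, 20, 6 and 218 without ERβ vehicle replicate 1 and 2 and ERβ 48 h replicate 1 and 2. At 8 h 2 were called and at 4 h 0, with 972 and 837 at unadjusted p under 0.05. At 8 h it was 28 without ERα vehicle replicate 2, 0 without ERα 8 h replicate 2 or ERβ vehicle replicate 1, and 1 without ERα vehicle replicate 1, ERα 8 h replicate 1, ERβ vehicle replicate 2 or ERβ 8 h replicate 2. At 4 h it was 41 without ERβ 4 h replicate 1 and at most 6 without any other array.

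The F test over the 4 times, which tests the difference once per probe set and named KRT19, MSMB, PODXL, ENPP2 and BMP5, called 8. This count also moved with several settings of the processing, among them the filter and the spike-in covariate, as given below. Without single arrays it was 2 without ERα 8 h replicate 2, ERα 48 h replicate 1 or ERα 48 h replicate 2. It was 3 without ERα vehicle replicate 1, ERα 24 h replicate 1, ERα 24 h replicate 2 or ERβ vehicle replicate 1, and 4 without ERβ 24 h replicate 2. It was 5 without ERα 4 h replicate 1, ERα 8 h replicate 1, ERβ vehicle replicate 2 or ERβ 24 h replicate 1. It was 16 without ERβ 48 h replicate 2, 33 without ERα vehicle replicate 2 and 39 without ERβ 4 h replicate 1.

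Most probe sets called in both lines moved the same way. At 48 h 39 probe sets rose in both lines against 5.53 under independence (the product of the counts over 7535), 13 fell in both against 1.01, and 1 went opposite ways. CCN5, MSMB, TFF1, TCN1 and ENPP2 were among those that rose in both, while KRT19 in ERβ cells had 0.89 with adjusted p 0.050, not past the threshold. Of the 127 probe sets called in ERβ cells, 106 had the same sign in ERα cells, while 403 of the 685 called in ERα cells had the same sign in ERβ cells. At 24 h 65 of 77 ERβ calls had the same sign in ERα cells, but 358 of 794 ERα calls had the same sign in ERβ cells. Across all genes, which are not independent replicates, r between the lines was 0.24 at 48 h, 0.08 at 24 h, -0.0064 at 8 h and -0.073 at 4 h. These signs and r values are on the authors' scale, where dim and bright probe sets drifted opposite ways in the lines at 24 h. They were not recomputed with quantile normalization, so little sharing between the lines cannot be told apart from this drift. Within a line, 24 and 48 h share their vehicle arrays. In ERα cells 414 rose at both times against 41.0 under independence and 97 fell against 4.36, and in ERβ cells 48 and 7 against 0.629 and 0.108. Simulated data with no effect and the same shared vehicle gave a covariance of 0.0258 and r of 0.50. ERα cells had 0.0974 and 0.83 and ERβ cells 0.0617 and 0.69, so part of the excess may come from the shared controls. The simulation gave 0.01 shared calls on average, but without effects almost nothing is called, so this is no reference for the shared counts. Its noise was independent between probe sets, while 21.8% of the residual variance in these data lay along 1 shared axis.

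**Figure D3:**
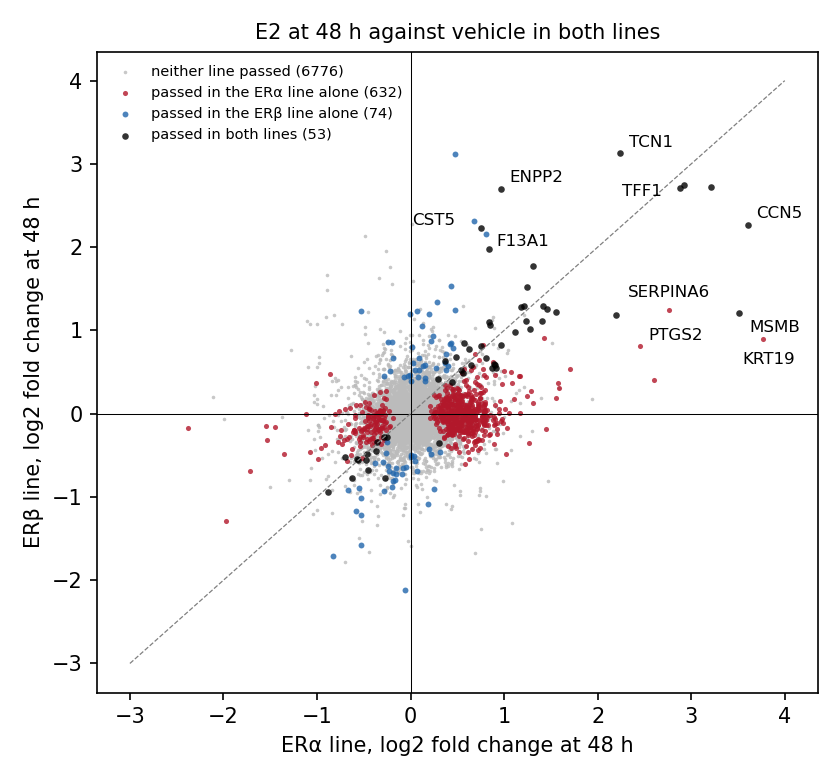
Log2 change with E2 at 48 h in the ERβ line (vertical axis) against the ERα line (horizontal axis), 1 point per probe set, coloured by whether it passed in the ERα line alone (632), the ERβ line alone (74), both (53) or neither (6776). KRT19 and MSMB lie toward the ERα axis and ENPP2 toward the ERβ axis, while TFF1 and TCN1 lie near the diagonal.

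Comparing the late mean with the early mean removes the vehicle arrays. In ERα cells TFF1 rose from early to late by 2.31, CCN5 by 2.28, MSMB by 2.21 (SE 0.17, adjusted p 7.7e-06) and TCN1 by 1.56. In ERβ cells TCN1 rose by 2.15 (SE 0.13, adjusted p 9.1e-07), TFF1 by 1.73 and CCN5 by 1.48, while MSMB had 0.72 with adjusted p 0.067, not past the threshold. By time, MSMB had 0.47, 0.91, 2.30 and 3.51 at 4, 8, 24 and 48 h in ERα cells. TCN1 had 0.05, 0.42, 1.64 and 3.13 in ERβ cells. Late against early called 219 probe sets in ERα cells (156 rose) and 74 in ERβ cells (54 rose), and 25 rose in both lines against 1.12 under independence. The ERα count was 118, 96, 47, 76, 70, 61 and 85 without 4 h replicate 1, 8 h replicate 1, 8 h replicate 2, 24 h replicate 1, 24 h replicate 2, 48 h replicate 1 and 48 h replicate 2. The ERβ count ran from 43 without 24 h replicate 1 to 186 without 4 h replicate 1.

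The estrogen response list was the one that passed in both lines at the preset correlation. With the correlation estimated it passed in the late mean of ERβ cells alone. Of its 30 genes tested, 9 rose in the late mean in ERα cells and 0 fell: TFF1, GREB1, MYBL1, KRT19, NRIP1, CA12, RET, OLFM1 and CCN5. GREB1, a cofactor of estrogen receptors, rose by 1.39 and NRIP1 by 1.13. In ERβ cells 8 rose, among them CTSD, a lysosomal protease, by 0.51, XBP1, a factor of the unfolded protein response, by 0.23 and HSPB1, a small chaperone, by 0.32. The late camera test gave adjusted p 0.0029 in ERα cells and 2.6e-06 in ERβ cells, with estimated-correlation adjusted p 0.067 and 0.019. The early tests gave adjusted p 0.00051 and 0.0029, with estimated-correlation adjusted p 0.054 and 0.067. Adjusted over the list alone, 9 rose in ERα cells and 11 rose and 1 fell in ERβ cells in the late mean. The early test in ERβ cells gave adjusted p 0.070 without ERβ vehicle replicate 2. The difference between lines did not pass for this list (adjusted p 0.82 late).

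In the late mean in ERα cells 5 of 16 interferon genes fell and 0 rose. Those that fell were IFITM2, LGALS3BP and the antigen-processing genes PSMB8, PSMB9 and TAP1, while IFIT5 had 0.47 and OAS2 0.34, neither past the threshold. PSMB8 fell by 0.77 and LGALS3BP, a secreted glycoprotein, by 0.37 at 24 h. The median over the list was -0.24, with camera adjusted p 0.030 and estimated-correlation adjusted p 0.21. The early mean gave adjusted p 0.023 and estimated-correlation adjusted p 0.19, and the lines differed early with adjusted p 0.036 (estimated-correlation adjusted p 0.23). Without the filter the interferon tests gave adjusted p 0.068 late and 0.057 early. Without ERα vehicle replicate 2 they gave 0.14 late and 0.15 early, and without ERα 4 h replicate 2 the early test gave 0.057. The difference between lines lost its call with the mean of probe sets per gene and without any 1 of 5 arrays. These were ERα vehicle replicate 2, ERα 4 h replicate 2, ERβ vehicle replicate 2, ERβ 4 h replicate 1 and ERβ 8 h replicate 2 (adjusted p up to 0.24). Of 16 ribosome biogenesis genes, NOP2, FBL, POLR1C, BYSL and IMP4 fell and DDX21 rose, with adjusted p 0.026 and estimated-correlation adjusted p 0.18. The lines differed late for the ribosome list with adjusted p 0.041 (estimated-correlation adjusted p 0.19). Adjusted over the list alone, 6 interferon genes fell and 1 rose, and 8 ribosome genes fell and 1 rose. With quantile normalization the ribosome tests gave adjusted p 0.091 in ERα cells and 0.19 between lines, past the threshold no longer. Without ERα vehicle replicate 1 they gave 0.080 and 0.12. The difference between lines for this list also lost its call with the stricter filter (0.090) and without ERα 24 h replicate 1, ERα 48 h replicate 2, ERβ vehicle replicate 2, ERβ 4 h replicate 2, ERβ 24 h replicate 1 or ERβ 48 h replicate 2.

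Of 20 amino acid and stress response genes, SLC7A5 alone rose in the early mean in ERβ cells, where the list test pointed up with adjusted p 0.010 and estimated-correlation adjusted p 0.19, and adjusted p 0.070 without ERβ vehicle replicate 2. HERPUD1, a gene of the unfolded protein response, and XBP1 rose in the late mean, where the list gave adjusted p 0.14. Of 34 DNA replication genes 0 passed in limma in the early mean, where the list test pointed up with adjusted p 0.030 and estimated-correlation adjusted p 0.50. That call was lost without the filter (0.057) and without ERβ vehicle replicate 2 (0.74), ERβ 4 h replicate 2 (0.12) or ERβ 8 h replicate 1 (0.11). In all, 11 of 144 list tests passed, and 1 passed with the correlation estimated. The 11 were 6 without ERβ vehicle replicate 2. Adjusted over the list alone, 3 stress genes and 0 replication genes passed in the early mean.

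The other lists did not pass. In ERα cells the late mean had 7 matrix and adhesion genes up and 4 down (of 42; adjusted p 0.94), with LUM, a collagen-binding proteoglycan, up by 0.53, FN1, fibronectin, by 0.50 and LAMB1, a laminin chain, by 0.29. In ERβ cells 1 matrix gene rose, ITGA6, and 4 fell, which were TNC, TGFBI, FBN1 and LOXL1 (adjusted p 0.34). Mitosis genes in ERα cells split 4 up and 3 down (of 32; adjusted p 0.88), with CDK1, TOP2A, KIF14 and CENPF up and AURKB, CDC20 and UBE2C down. The TGF-beta, BMP and WNT list split 4 and 4 in ERα cells (of 34, adjusted p 0.75), with SFRP1, a WNT antagonist, up and ID1 and ID3, targets of BMP, down. In ERβ cells it split 3 and 2 (adjusted p 0.66), and GREM1, a BMP antagonist, rose by 2.31. That value is of the late mean alone, and GREM1 was not among the 12 rises named by the rule in ERβ cells. Coregulators split 3 and 2 in ERα cells (of 17; adjusted p 0.88) and 0 and 1 in ERβ cells (adjusted p 0.14). NF-kappaB genes had PTGS2 up and NFKBIA, NFKBIE and TNFAIP2 down in ERα cells (of 16; adjusted p 0.70), and NFKB2 down in ERβ cells (adjusted p 0.70). Immediate early genes had CCN1 up and IER2, ID1 and ID3 down (of 23; adjusted p 0.67), with a test pointing down and a median of 0.07.

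For the remaining lists, the ERα and ERβ late means gave these results. Hypoxia and glycolysis, of 26, had 2 up and 3 down (adjusted p 0.65) and 2 up and 1 down (adjusted p 0.82), with SLC2A3 down and CA12 up in both lines. Heat shock, of 14, had 3 up and 2 down (adjusted p 0.78) and 1 up (HSPB1; adjusted p 0.34). Cholesterol synthesis, of 16, had 2 up and 2 down (adjusted p 0.78) and 0 either way (adjusted p 0.86). The p53 list, of 18, had FAS and PPM1D up and GADD45B down (adjusted p 0.70) and 1 down (adjusted p 0.099). Apoptosis regulators, of 24, had FAS up and BIK and TNFRSF1A down (adjusted p 0.39) and 0 (adjusted p 0.50). Growth factors, of 28, had IGFBP6 and GAS6 down (adjusted p 0.77) and IGFBP5 up (adjusted p 1.00). The bone list, of 14, had BMP6 up and BMP4 down (adjusted p 0.77) and 0 (adjusted p 0.79). The retinoid list, of 9, had DHRS3 down (adjusted p 0.55) and TGM2, a transglutaminase, up (adjusted p 0.70). Epithelial genes, of 17, had KRT19 up and KRT18 down (adjusted p 0.84) and KRT19 up (adjusted p 0.34). Neural genes, of 10, had NCAM1 up and TUBB3 down (adjusted p 0.67) and 0 (adjusted p 0.65). The muscle and fibroblast list, of 14, had CALD1 up (adjusted p 0.34) and CNN1 down (adjusted p 0.54). Blood (5 genes; adjusted p 0.70 and 0.86) and endothelial (2 genes; adjusted p 0.97 and 0.70) lists had 0 in limma, where the unadjusted counts over all genes were 1911 at 24 h in ERα cells and 888 in ERβ cells. The late mean in ERα cells had 2 stress genes up (adjusted p 0.79), and 1 replication gene up and 2 down (adjusted p 0.80). In ERβ cells the immediate early (adjusted p 0.78), mitosis (0.70), replication (0.64), interferon (0.94) and ribosome (0.81) lists had 0 genes past the threshold. In ERα cells the test pointed down while the mean was above 0 for the epithelial, matrix, mitosis, neural, growth factor, hypoxia, NF-kappaB, immediate early, TGF-beta, bone and replication lists. In ERβ cells it pointed up while the mean was below 0 for the retinoid, interferon and ribosome lists. The test and the median differed in sign in ERβ cells for the retinoid, interferon, hypoxia, blood and immediate early lists, and in ERα cells for the immediate early, replication, mitosis, matrix, growth factor, TGF-beta and NF-kappaB lists. Tests of the early mean and of the difference between lines passed for the lists named earlier and for no other list.

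Without hormone the lines differed widely. AEBP1, a secreted matrix protein, read 58.6 ± 9.4 in ERα cells and 3506 ± 506 in ERβ cells (log2 difference 4.08, SE 0.19, adjusted p 5.9e-09), and CCN5 was higher in ERβ cells by 3.10. COL1A1, the main collagen of bone, read 6950 ± 1075 in ERα cells and 410 ± 207 in ERβ cells (log2 difference -3.69), and KRT75, a keratin of the hair follicle, 6903 ± 359 and 773 ± 2.33. Limma called 3280 of 7535 probe sets, of which 1969 were higher in ERβ cells. At 2-fold or more, 514 were higher in ERβ cells and 228 in ERα cells. Leaving out 1 array gave 2457 to 2776. These genes were named after their values were seen.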

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

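The tests of the ERα vehicle arrays and of replicate spread were chosen only after the result was seen, while the splits of arrays and the test of scale were planned. The results here are those where the E2 effect differed between the lines by the F test. KRT19 gave -3.03 at 24 h (ERβ effect minus ERα effect, log2; SE 0.30, adjusted p 0.0015), the clearest of them. MSMB gave -2.30 at 48 h (SE 0.34, adjusted p 0.049). PODXL gave -0.85 at 24 h (SE 0.11, adjusted p 0.022), and BMP5, a bone morphogenetic protein, -0.92 at 48 h (SE 0.14, adjusted p 0.049), with 0.66 in ERα cells and -0.26 in ERβ cells. The BMP5 difference at 48 h lost its call without ERα vehicle replicate 1, ERα 48 h replicate 1, ERβ vehicle replicate 1 or ERβ 48 h replicate 1 (adjusted p up to 0.082). Of the ENPP2 probe sets, 2 gave 1.74 and 1.48 at 48 h, with adjusted p 0.021 and 0.011, and the dimmest gave 0.16 (SE 1.42, adjusted p 0.98). Among probe sets with several symbols, 1 gave -1.04 at 24 h (adjusted p 0.043) and 1 gave 2.65 at 48 h (adjusted p 0.036).

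The pattern weighed here is that more probe sets changed in ERα cells (794 at 24 h) than in ERβ cells (77). Late against early, which needs no vehicle, called 219 and 74, but this ratio of 2.96 ran from 0.681, a reversal seen without ERα 8 h replicate 2, to 5 with 1 E2 array left out. Uneven scale of the ERα vehicle arrays as the whole cause was argued against by quantile normalization, which left a ratio of counts of 7.55 at 24 h. Vehicle arrays that stand apart would move all E2 times alike, but the signed change of the genes called at 48 h reached 0.446 of the 24 h value at 4 h and 0.568 at 8 h, so a part shared by all times may remain (the 24 h count was 119 without ERα vehicle replicate 1). Lower replicate spread in ERα cells was argued against by a 1.96-fold larger net root mean square change at 24 h (0.253 against 0.129) and 1.54-fold at 48 h. Receptor and clone stay open as biological explanations, untested because each receptor is in 1 line.

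The comparison of late with early arrays was set against other splits of the arrays. Of the 35 splits of the 8 E2 arrays of the ERα line into 4 and 4, 1, the real one, called as many probe sets (248 in that fit, against 10 in the highest other split). In the ERβ line it was also 1 of 35, with 35 against 5. Chance can be excluded for both lines only if all arrays are independent, which the labels do not say, and 1 of 35 is the smallest share that these splits can give.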

How the results depend on the processing

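Most values kept their direction and their side of the threshold. Apart from leaving out arrays, 145 of the counts stayed within 1.5 times and 51 moved, 1448 gene values stayed and 233 lost their call, and 102 list tests stayed and 17 lost it. With arrays left out, 58 counts stayed and 86 moved, 380 gene values stayed and 370 lost their call, and 199 list tests stayed and 21 lost it. A group then has 1 array, which is assumed to vary like the other groups. A single value reversed: NOS3 in ERβ cells at 24 h, at -0.33 and not past the threshold, ran from -0.80 to 0.14 with 1 array left out (adjusted p 0.88 at 0.14, without 24 h replicate 1).

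The counts at 4 h and of the difference between lines moved with several settings. For ERα at 4 h (8), quantile normalization, median centring, the replicate block and the crossed pairing (added) each gave 4, and no trend gave 5. For ERβ at 4 h (5), the smaller offset gave 2, no filter 12, the stricter filter 1 and the replicate block 1. For the difference between lines (8), the smaller offset gave 5, quantile normalization, median centring and the block 4 each, no filter 26 and the spike-in covariate (added) 1. At single times (0, 2, 229 and 84 at 4, 8, 24 and 48 h), the difference at 8, 24 and 48 h gave 0, 44 and 33 with quantile normalization, 0, 76 and 32 with median centring, and 0, 119 and 3 with the spike-in covariate. No filter gave 1, 4 and 139 at 4, 8 and 24 h, and the stricter filter 128 at 48 h. At 8 and 48 h no trend gave 0 and 54 and the replicate block 0 and 37. For the 0 at 8 h, limma had 972 at unadjusted p under 0.05 in the main setting. The cause was not tested for these.

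With each line fitted alone, fewer arrays set the spread, and fewer calls followed. ERα gave 4, 529 and 406 at 4, 24 and 48 h, 93 late against early and 74 in the F test. ERβ gave 0, 7, 34 and 48 at 4, 8, 24 and 48 h, 44 late against early and 33 in the F test. A minimum of 2-fold, which can remove calls but not add them, left 13, 49 and 52 in ERα at 8, 24 and 48 h, and 1, 5, 27 and 40 in ERβ at 4, 8, 24 and 48 h. With the correlation estimated per list, 1 list test passed in place of 11.

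Leaving out 1 array gave 4 to 14, 11 to 38, 119 to 733 and 120 to 675 in ERα at 4, 8, 24 and 48 h, and 0 to 91, 4 to 18, 32 to 42 and 47 to 205 in ERβ. The F tests gave 90 to 304 in ERα, 64 to 181 in ERβ and 2 to 39 for the difference, which at 4, 8, 24 and 48 h gave 0 to 41, 0 to 28, 3 to 389 and 1 to 221. Late against early gave 47 to 166 in ERα and 43 to 186 in ERβ, the lists 6 to 14, and the vehicle lines 2457 to 2776. The cause was not tested.

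The labels do not say whether the replicate numbers pair the arrays. In ERβ 4 of the E2 arrays carry no number in their titles and were taken as replicate 1. With the numbers so assigned, over 10 pairs of groups the deviations correlated from -0.32 to 0.26 in ERα, with 3 over 0.1, and from -0.04 to 0.19 in ERβ, with 4 over 0.1. The replicate block gave 719 and 665 in ERα and 75 and 116 in ERβ at 24 and 48 h. The crossed pairing in ERα, chosen after seeing the data, gave 27, 824 and 726 at 8, 24 and 48 h, and the spike-in covariate was also chosen after seeing the data. Signal over background limits the genes near or below the offset, among them 5 of the 12 named falls in ERα and 2 of 12 in ERβ.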

Other observations

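The tests of brightness and RNA degradation in this part, and the comparison of gene lists between vehicle arrays, were chosen only after the result was seen. Without hormone, of 20 unfolded protein and amino acid response genes, 13 were higher in ERα cells and 1 in ERβ cells (camera adjusted p 2.3e-05, estimated-correlation adjusted p 0.038). Of 34 DNA replication genes, 17 were higher in ERα cells and 3 in ERβ cells (adjusted p 0.00026, estimated-correlation adjusted p 0.20). Matrix genes split 22 and 11 (adjusted p 0.025, estimated-correlation adjusted p 0.43), and epithelial genes 9 and 0 (adjusted p 0.027, estimated-correlation adjusted p 0.20). The amino acid response and replication lists also pointed up in the early mean of ERβ cells, against the same ERβ vehicle arrays. A low reading of those arrays would give both results, so they are not independent. POLD1, a replication polymerase that fell with E2 in ERα cells, was higher in those cells without hormone (ERβ minus ERα, log2: -3.48). GAS1, which fell with E2 in ERβ cells, was higher in those cells by 2.33, and LIMCH1 by 3.71. Each fall and each difference use the same vehicle arrays, so a high vehicle reading would give both. POLD1 read -127 in ERβ vehicle and LIMCH1 36.1 in ERα vehicle, so a fall there could hardly show. No link between fall and starting level can be drawn from these genes. ID2, an inhibitor of differentiation, was higher in ERβ cells by 2.50, and PDGFB, a growth factor, was higher in ERα cells (-2.69). Receptor and clone run together here, and array measures differed too: the vehicle arrays of the ERα line read 18.7 and -25.6 on the 18S rRNA controls, and those of the ERβ line 747 and 272. The 3' to 5' ratio of GAPDH was 1.05 and 1.03 against 0.975 and 1.01, and the BioB spike-in read 15518 and 24453 against 27241 and 24807. No test separated these measures from the line of cells.

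The pattern weighed here is that the replicates of a group deviate along a shared axis. Over the 10 pairs of replicates, the difference in the first residual component followed the difference in spike-in level, with Pearson r -0.848 (permutation p 0.0017, adjusted over 2 measures 0.0033) and Spearman rho -0.867 (permutation p 0.0020). Without the 2 farthest pairs r was -0.748. The 3' to 5' ratio gave r 0.424 (permutation p 0.23) and rho 0.467 (permutation p 0.18), with 0.202 without the 2 farthest. Target brightness may therefore underlie part of the replicate spread, while for degradation 10 pairs decide nothing.

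The negative list test of interferon genes in ERα cells was tested against an effect of the vehicle arrays with a prediction written before. The median late minus early change of the 16 genes was -0.0852 (camera p 0.0662). The genes had a median of -0.13 early and -0.24 late, with 11 of 16 below 0 late. Without vehicle replicate 1 the late median was -0.19, and without vehicle replicate 2 it was -0.22. A vehicle effect cannot be told apart from an early E2 effect for these genes, since part of the shift was there at the early times, and it may be either. The list call itself was lost with the correlation estimated (adjusted p 0.21), without the filter (0.068) and without vehicle replicate 2 (0.14).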
